A study of Mus musculus with 24 samples.

How the data were processed

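Primary microglia, the resident macrophages of the brain, were prepared from the cortex and hippocampus of newborn wild-type mice, per the labels' protocols. Mixed glial cultures were grown to near confluency and the microglia were then shaken off, so that other glia carried over with them cannot be ruled out from the protocol. The cells received 50 nM bafilomycin A1 (BafA1), an inhibitor of the vacuolar proton pump (V-ATPase) that acidifies lysosomes, or the vehicle DMSO, and RNA was taken after 1, 7, 14 or 22 h. Each of the 8 combinations of treatment and time had 3 replicates, 24 libraries in all. The series design calls these biological replicates. It does not say which litters or flasks they came from, so p-values measure the spread between these samples.

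Libraries were made with a 3′ tag kit (QuantSeq FWD) that adds unique molecular identifiers to remove PCR duplicates, and were sequenced as 75 bp single-end reads, per the labels' protocols. The submitters' processing notes name Salmon, with no version, and the GRCm39 build; the annotation release and how duplicates were removed are not given in the sources used here. The authors deposited estimated counts per gene, of which 37.1% of the values above 0 were not whole numbers, and a table of log2 CPM (counts scaled to a fixed library total). The deposited log2 CPM values differed from log2 CPM recomputed from the counts by at most 0.0012, so the deposited counts served for all tests. The estimated counts were rounded to whole numbers first. A 3′ tag reads out the end of a transcript and gives no isoform, and genes with near-identical copies can share reads. Rn7sk and any copies of it, H2ac7, Clec4a1, Clec4b1 and Pcdhga8 are therefore uncertain wherever they are named. No coordinates are given, because the reference annotation used here is of build GRCm38 and not GRCm39; it supplied transcript lengths by gene ID for a single check. In the count table, 293 gene IDs shared a symbol with another ID.

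Genes were kept by edgeR's filterByExpr with the 8 groups, which left 12648 of 56980 genes for testing; the genes left out held 0.7% of all counts. Libraries were scaled by TMM factors. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) over all 24 samples with 1 coefficient per group. BafA1 was compared with DMSO at the same time, so that no DMSO library served at more than 1 time. The BafA1 effect was compared between successive times, and over all times together by an F test of treatment by time. The DMSO cultures at 7, 14 and 22 h were compared with those at 1 h, and those 3 comparisons share the 1 h libraries. Adjusted p means the Benjamini-Hochberg value over all genes tested unless stated otherwise, and a gene was called at an adjusted p under 0.05. Fold changes are given on the log2 scale with the standard error (SE) of the fit, and levels as mean CPM ± SD with n = 3. Where every library of a group was at 0, a fold is a bound against a floor of 3 counts over the group.

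The gene lists, 32 in all, were fixed before the data were examined. They cover V-ATPase and lysosome, autophagy, nutrient sensing, sterol and lipid metabolism, hypoxia and glycolysis, metals, stress responses, inflammation and interferon, microglial states, cell division, mitochondria, ribosomal proteins, and markers of astrocytes, the oligodendrocyte lineage, neurons, fibroblasts and vessels, and border macrophages. Each list was tested in each BafA1 comparison with camera on log2 CPM (prior count 2, preset correlation 0.01, two-sided, Benjamini-Hochberg over all lists and times). Camera with an estimated correlation and fry were run as alternatives. Lists also carry a count adjusted over the list alone. Camera tests of lists between successive times were chosen after the data were seen.

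Genes named in the text followed a rule fixed before the data were examined. It took the 10 largest rises and 10 largest falls per BafA1 comparison among called genes with a mean log2 CPM of at least 3, a proper symbol and no overlap between the 3 BafA1 and the 3 DMSO values. It also took up to 4 called members per list with the largest change (or the 2 most abundant members where fewer than 2 were called), which could be followed at the other times, the 10 genes with the smallest p of the treatment by time test, and the 5 largest DMSO changes each way at 22 h (3 at 7 h and 14 h). Genes named outside it are said to have been chosen after their values were seen. Some genes that the rule selects are not reported.

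Library totals ran from 1322169 to 4189077 counts, so that 3 counts, the floor for a gene seen at 0 in 1 library, correspond to 0.77 to 2.4 CPM. Such floors cover counting error only. On data simulated from these libraries, the same test over 12648 genes recovered 58%, 69%, 69% and 62% of 100 genes changed 2-fold at 1, 7, 14 and 22 h, and 89%, 96%, 95% and 95% of 100 genes changed 4-fold. Of its calls there, 3.92%, 5.71%, 7.87% and 5.42% were unchanged genes. The changed genes were drawn from those with a mean log2 CPM of at least 3, and each gene had 1 spread for all groups. Recovery of genes with lower counts, or in a group with a wider spread, was not measured. The simulation changed as many genes up as down and drew each library independently. It changed far fewer genes than the 3054 and 5050 called at 14 and 22 h in the real data. The shares of unchanged genes among its calls therefore need not hold for the real comparisons. Replicates were compared for repeated libraries: the chi-square per degree of freedom of the 24 replicate pairs ran from 4.17 to 11.5, so none agreed within sampling noise.

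Groups share replicate numbers 1 to 3 in the labels. In the deviations from group means over 9258 genes, the 12 DMSO and BafA1 libraries of the same number and time correlated at r = 0.201 to 0.412, against at most 0.137 for different numbers, so the numbers were taken to pair the libraries. Over all 28 pairs of groups, 23 had every same-number correlation above 0.1. The main test leaves the pairing out, as fixed beforehand, and a fit with the replicate number as a block was run beside it. The other alternatives were RLE size factors, no count filter, a stricter filter, DESeq2 1.42.0, limma-voom, only the 6 libraries compared, and each library left out in turn. Thinning every library to the smallest total of 1322113 rounded counts was added after the data were seen, because the BafA1 libraries at 14 and 22 h were deeper than the DMSO ones.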

Results

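Gene expression was measured in primary mouse microglia after 1, 7, 14 and 22 h with 50 nM BafA1, which blocks the V-ATPase and so raises lysosomal pH, or with DMSO, with 3 libraries for each treatment and time. Library totals ranged from 1322169 to 4189077 counts. At 14 and 22 h they ran from 2805274 to 4189077 with BafA1 and from 1332093 to 3056773 in DMSO. In each library 18232 to 22416 genes had at least 1 count. RNA integrity numbers were 9.6 to 10 where given. Mitochondrial genes took 3.29% to 5.35% of counts and ribosomal protein genes 7.49% to 11.2%.

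The first question was how soon lysosomal alkalinization is seen in the transcriptome. After 1 h with BafA1 no gene of the 12648 tested was called by edgeR's quasi-likelihood test, in either direction. Atp6v1a, the catalytic subunit of the V-ATPase, differed by a log2 change of 0.02 ± 0.14 (SE), and Psap, the precursor of the saposins that help degrade sphingolipids in lysosomes, by 0.10 ± 0.18. The 17 V-ATPase subunits had a median log2 change of 0.05 and the 47 lysosomal genes one of 0.06, with camera adjusted p = 0.609 and 0.722. The lysosomal list was called in both directions when 1 library was left out: lower without DMSO 1 h replicate 3 (adjusted p = 0.0429), and higher without DMSO 1 h replicate 1 (0.0297) or BafA1 1 h replicate 3 (0.00132). The type I interferon response was lower as a list by camera, with a median of -0.14 over 22 genes (adjusted p = 0.0374), as were the nuclear-encoded genes of oxidative phosphorylation, with a median of -0.07 over 33 genes (adjusted p = 0.0377). None of their members was called, also when adjusted over the list alone, and the most abundant members were Trim30a (-0.19 ± 0.19) and Cox6c (0.08 ± 0.14). Neither list call held with an estimated correlation (adjusted p = 0.529 and 0.563). The interferon call also ended without DMSO 1 h replicate 1 (adjusted p = 0.1), DMSO 1 h replicate 2 (0.14) or BafA1 1 h replicate 3 (0.614), and with the stricter filter (0.0886) or in thinned libraries (0.128). The oxidative phosphorylation call ended without DMSO 1 h replicate 2 (0.294) or 3 (0.0509) or BafA1 1 h replicate 1 (0.384) or 3 (0.0552), and with the stricter filter (0.065). At an unadjusted p under 0.05 the test found 380 genes. RLE scaling, limma-voom, DESeq2 and the fit of only the 6 libraries also called 0 genes, and leaving the low-count genes in gave 26 calls.

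After 7 h with BafA1, genes of hypoxia, glycolysis and cholesterol synthesis had risen together. Fabp4, a fatty acid binding protein of macrophages and adipocytes, had the largest rise among the genes chosen by the naming rule, from 9.58 ± 5.3 to 141 ± 11.2 CPM (SD, n = 3; log2 change 3.82 ± 0.28, adjusted p = 2.82e-09). Of 27 hypoxia and HIF target genes 18 rose and 1 fell (20 and 1 adjusted over the list alone; camera adjusted p = 1.16e-21). Bnip3, a mitophagy receptor, rose by 2.52 ± 0.20, the lactate exporter Slc16a3 by 2.26 ± 0.19, the endoplasmic reticulum oxidase Ero1a by 2.24 ± 0.21, and Hilpda, which inhibits lipolysis at lipid droplets, by 2.18 ± 0.26. The member that fell was Pfkfb4, which makes a regulator of glycolytic flux (-1.78 ± 0.33). Glycolysis genes moved alike, 12 of 19 rising and none falling (15 and 1 adjusted over the list alone; adjusted p = 1.32e-17). Tpi1 rose by 1.83 ± 0.17, Pfkl by 2.05 ± 0.22 and hexokinase 2 (Hk2) by 1.70 ± 0.18.

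Cholesterol synthesis genes and SREBP2 targets rose in 18 of 24 cases at 7 h, with none lower (20 and 0 adjusted over the list alone; median 0.99, camera adjusted p = 1.16e-21). Idi1 rose by 1.38 ± 0.25, Acat2 by 1.35 ± 0.18 and Hmgcs1, which makes HMG-CoA, by 0.94 ± 0.12, from 303 ± 25.8 to 584 ± 35.9 CPM. Fatty acid synthesis genes rose in 5 of 16 cases (7 adjusted over the list alone; adjusted p = 2.11e-05), among them Acsl3 at 1.2 ± 0.17 and Fasn, the fatty acid synthase, at 1.01 ± 0.21. The first list held with an estimated correlation (adjusted p = 0.000134), as did hypoxia (0.000113) and glycolysis (0.00625), and the fatty acid list did not (adjusted p = 0.0676). Of 18 genes of lipid storage and uptake, 5 rose and 1 fell (7 and 2 adjusted over the list alone). Fabp5 rose by 1.61 ± 0.17 and Soat1, which esterifies cholesterol, by 1.44 ± 0.20, while the lipase Lpl fell by 0.90 (SE 0.15). The median of that list was -0.01, its mean 0.43 and its camera direction higher (adjusted p = 0.0386, and 0.529 with an estimated correlation). The call ended without DMSO 7 h replicate 3 (adjusted p = 0.0694) or BafA1 7 h replicate 1 (0.17).

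The V-ATPase itself was among the groups that rose at 7 h, with 9 of 17 subunits higher and none lower (13 and 0 adjusted over the list alone; camera adjusted p = 1.54e-10, and 0.0529 with an estimated correlation). Atp6v1a rose from 602 ± 62.4 to 1510 ± 163 CPM (1.33 ± 0.14) and Atp6v1c1 by 1.39 ± 0.17. Lysosomal enzymes and membrane proteins were less uniform: 10 of 47 rose and 1 fell (14 and 1 adjusted over the list alone; adjusted p = 0.000519). Gla, the α-galactosidase, rose by 1.5 ± 0.18 and the cholesterol exporter Npc1 by 1.01 ± 0.16, and the protease Ctsc fell by 1.15 (SE 0.22). That list call was lost with an estimated correlation (adjusted p = 0.696) and without DMSO 7 h replicate 3 (adjusted p = 0.098). Among MiT/TFE factors and mTORC1 nutrient sensing genes 7 of 25 rose and 1 fell, the same numbers when adjusted over the list alone (camera adjusted p = 0.088, and 0.0228 without DMSO 7 h replicate 1, with a median of -0.004 and a mean of 0.195). Those that rose included the Rag GTPase genes Rragd (2.31 ± 0.23) and Rragc (1.1 ± 0.14) and the folliculin partner Fnip2 (1.78 ± 0.22), and the one that fell was Sesn1 (-1.25 ± 0.23). Autophagy genes had 3 of 35 higher (4 higher and 1 lower adjusted over the list alone; adjusted p = 0.0136, and 0.349 with an estimated correlation). Tecpr1 was at 1.96 ± 0.23 and the cargo receptor Sqstm1 at 0.82 ± 0.12. This call ended without DMSO 7 h replicate 3 (0.0777) or BafA1 7 h replicate 1 (0.0676). Of 30 genes of the integrated stress response 8 rose (16 adjusted over the list alone; adjusted p = 5.21e-09, and 0.0286 with an estimated correlation), Atf4 by 1.44 ± 0.19, Chac1 by 2.42 ± 0.54 and Gdf15 by 1.68 ± 0.32. NRF2 targets rose in 5 of 19 cases (6 adjusted over the list alone; adjusted p = 0.00728, and 0.19 with an estimated correlation). Inflammatory genes rose in 3 of 24 with 1 lower (8 and 1 adjusted over the list alone; adjusted p = 0.00391, and 0.192 with an estimated correlation). The chemokines Ccl4 (1.3 ± 0.26) and Ccl3 (1.17 ± 0.22) rose and the cytokine Il1b fell by 1.58 (SE 0.34).

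Among falling genes at 7 h, Rn7sk, the small nuclear RNA that holds the elongation factor P-TEFb inactive, went from 278 ± 118 to 32.3 ± 9.97 CPM (-3.11 ± 0.40, adjusted p = 6.63e-06). Rn7sk may share reads with near-identical copies. The organic anion carrier Slco2b1 fell by 2.79 (SE 0.30), Ppfia4 by 2.06 (SE 0.36) and Hpgd, which inactivates prostaglandins, by 1.98 (SE 0.28). Homeostatic microglia genes fell in 6 of 30 cases and 1 rose (10 and 2 adjusted over the list alone; camera adjusted p = 0.000646, and 0.501 with an estimated correlation). The fractalkine receptor Cx3cr1 fell from 2500 ± 388 to 1150 ± 147 CPM (-1.12 ± 0.20) and the transcription factor Mef2c by 1.43 (SE 0.26). Disease-associated microglia genes had 5 of 30 higher and 2 lower (7 and 2 adjusted over the list alone). Camera called that list higher (adjusted p = 0.0198, and 0.696 with an estimated correlation). The call ended without DMSO 7 h replicate 3 (0.218) or BafA1 7 h replicate 1 (0.0555) or 2 (0.132). Markers of oligodendrocyte precursors, another glial cell type, fell at the same time: 4 of 12 oligodendrocyte lineage markers (5 adjusted over the list alone; adjusted p = 0.000411, and 0.0676 with an estimated correlation). Pdgfra went from 126 ± 12.7 to 62.2 ± 11.5 CPM. No astrocyte, neuron or border macrophage marker was called at 7 h by edgeR. The endothelial marker Pecam1, also found on macrophages, was the 1 of 9 fibroblast and vascular markers that fell (-2.23 ± 0.48). Type I interferon genes fell in 3 of 22 cases (5 adjusted over the list alone; adjusted p = 0.00248, and 0.346 with an estimated correlation). This list call ended without BafA1 7 h replicate 3 (adjusted p = 0.0519).

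In all, 903 genes were called at 7 h, 578 higher and 325 lower, of which 275 and 164 changed by more than 2-fold (edgeR quasi-likelihood test, Benjamini-Hochberg). With the replicate number as a block the count was 1555, and without DMSO 7 h replicate 1 it was 573. Cd28, one of the 10 largest rises (2.25 ± 0.53), lost its call without DMSO 7 h replicate 2.

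**Figure D1:**
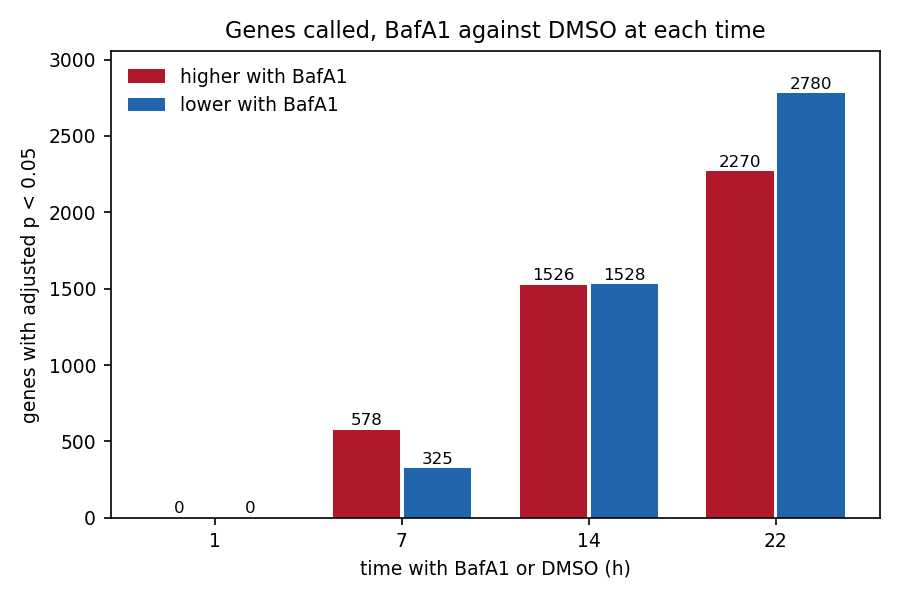
Bars give the number of genes called higher (red) and lower (blue) with BafA1 than with DMSO at each time in hours, from edgeR's quasi-likelihood test at an adjusted p under 0.05 with 3 libraries per group. The counts are 0 at 1 h, 578 and 325 at 7 h, 1526 and 1528 at 14 h, and 2270 and 2780 at 22 h.

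After 14 h the rises of hypoxia and glycolysis genes stood beside those of stress responses. P4ha2, a collagen prolyl hydroxylase on the hypoxia list, rose from 2.2 ± 1.35 to 59.2 ± 13 CPM (SD, n = 3; log2 change 4.76 ± 0.41, adjusted p = 3.36e-09). The cystine transporter Slc7a11 rose from 10.1 ± 1.79 to 225 ± 19.8 CPM (4.44 ± 0.25), the macrophage elastase Mmp12 from 39.2 ± 3.75 to 835 ± 216 CPM (4.41 ± 0.34), and Acod1, which makes itaconate, from 10.8 ± 1.01 to 142 ± 24.3 CPM (3.71 ± 0.24). Hypoxia genes now rose in 20 of 27 cases and fell in 1 (the same adjusted over the list alone; median 1.71, adjusted p = 5.62e-18). Glycolysis genes rose in 17 of 19 with 1 lower (the same adjusted over the list alone; median 1.43, adjusted p = 1.18e-16). Pgk1 rose by 2.25 ± 0.12 and Tpi1 by 2.46 ± 0.17. The glycolysis gene that fell was Aldoc (-1.82 ± 0.20), which is also on the astrocyte list. Of 30 integrated stress response genes 18 rose and 1 fell (19 and 1 adjusted over the list alone; adjusted p = 3.1e-12). Atf4 was at 2.23 ± 0.19, Trib3 at 3.44 ± 0.40 and Ddit3, the pro-apoptotic factor CHOP, at 2.52 ± 0.32. NRF2 targets, the antioxidant set, rose in 14 of 19 cases with none lower (the same adjusted over the list alone; median 0.98, adjusted p = 1.76e-12). Srxn1 was at 2.27 ± 0.15, Hmox1 at 2.03 ± 0.16 and Prdx1 at 1.94 ± 0.13. Endoplasmic reticulum chaperones rose in 16 of 22 cases with none lower (20 adjusted over the list alone; adjusted p = 4.76e-10), including Hspa5 (BiP) at 1.24 ± 0.11 and Hyou1 at 1.24 ± 0.15. All of these list calls held with an estimated correlation (adjusted p = 0.000134 for hypoxia, 0.00676 for glycolysis, 0.00941 for the integrated stress response, 0.00272 for NRF2 targets and 0.0099 for the chaperones).

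V-ATPase subunits rose in 14 of 17 cases at 14 h (15 adjusted over the list alone; median 0.84, adjusted p = 1.6e-10, and 0.0529 with an estimated correlation). Lysosomal genes rose in 18 of 47 with 3 lower (19 and 3 adjusted over the list alone; adjusted p = 0.000322, and 0.679 with an estimated correlation). Gla rose by 2.23 ± 0.18 and the macrophage-specific subunit gene Atp6v0d2 by 2.39 ± 0.39. Autophagy genes rose in 11 of 35 cases and fell in 1 (the same adjusted over the list alone; adjusted p = 0.00126, and 0.19 with an estimated correlation), led by Sqstm1 at 1.96 ± 0.12 and Optn at 1.90 ± 0.33, while Map1lc3b, the most abundant LC3 gene, was at 0.06 ± 0.13. Gpnmb, a MiT/TFE target, rose by 2.43 ± 0.27; on its list 7 of 25 rose and 1 fell, also when adjusted over the list alone (adjusted p = 0.0324, and 0.435 with an estimated correlation). The list call ended without DMSO 14 h replicate 3 (0.0625) or BafA1 14 h replicate 1 (0.0634), with the stricter filter (0.061) and in thinned libraries (0.0615). Cholesterol genes still rose in 11 of 24 cases with 1 lower (12 and 1 adjusted over the list alone; median 0.43, adjusted p = 0.000376, and 0.0676 with an estimated correlation). Lipid storage genes had 8 of 18 higher and 3 lower, also when adjusted over the list alone (adjusted p = 0.0127, and 0.43 with an estimated correlation). Inflammatory genes rose in 14 of 24 cases with 1 lower (16 and 2 adjusted over the list alone; median 0.93, adjusted p = 3.64e-06, and 0.0416 with an estimated correlation), among them Cxcl2 (2.33 ± 0.24), Tnfaip3 (2.14 ± 0.29) and Tnf (1.67 ± 0.28), while Il1b was lower (-1.73 ± 0.33). Type I interferon genes were split at 14 h, with 1 of 22 higher and 1 lower, also when adjusted over the list alone (camera adjusted p = 0.867).

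Homeostatic microglia genes fell in 19 of 30 cases at 14 h and 2 rose (the same adjusted over the list alone; median -0.94, adjusted p = 2.88e-08, and 0.192 with an estimated correlation). The purinergic receptor P2ry12 fell by 3.29 (SE 0.38), Gpr34 by 2.59 (SE 0.28) and Cx3cr1 by 1.66 (SE 0.20). Disease-associated microglia genes went both ways, 13 of 30 higher and 6 lower (15 and 6 adjusted over the list alone; adjusted p = 0.00932, and 0.672 with an estimated correlation). The galectin Lgals3 was at 2.90 ± 0.24 and Apoe at -1.02 ± 0.16. This call ended without DMSO 14 h replicate 3 (adjusted p = 0.0516). LXR targets fell in 7 of 15 cases, also when adjusted over the list alone (adjusted p = 0.0265, and 0.435 with an estimated correlation), the largest being Abca9 at -2.44 ± 0.35. The list call ended without BafA1 14 h replicate 3 (adjusted p = 0.0715). Cell cycle genes fell in 17 of 36 cases and 1, Pcna, rose (18 and 1 adjusted over the list alone; median -1.17, adjusted p = 5.4e-07, and 0.19 with an estimated correlation). Plk1 was at -2.80 ± 0.54 and Ccnb1 at -2.70 ± 0.38. Markers of other brain cells moved with these groups. Oligodendrocyte lineage markers fell in 8 of 12 cases, also when adjusted over the list alone (median -1.74, adjusted p = 5.45e-09, and 0.00652 with an estimated correlation). Pdgfra went from 108 ± 23.3 to 6.39 ± 1.9 CPM and Olig1 from 114 ± 5.19 to 11.5 ± 6.18 CPM. Astrocyte markers fell in 5 of 11 cases (6 adjusted over the list alone; median -0.92, adjusted p = 0.00391, and 0.43 with an estimated correlation). Neuron markers fell in 4 of 5 cases, also when adjusted over the list alone (adjusted p = 0.00248, and 0.0868 with an estimated correlation). Border macrophage markers fell in 3 of 7, also when adjusted over the list alone (camera adjusted p = 0.0639). They were called as a list without DMSO 14 h replicate 3 (0.0348) or BafA1 14 h replicate 1 (0.0481) and in thinned libraries (0.0329). Of the 10 largest falls at 14 h, Pdgfra, the proteoglycan Cspg5 (-3.73 ± 0.21), the neuroligin Nlgn3 (-3.65 ± 0.44) and Sox8 (-3.37 ± 0.31) are known from oligodendrocyte precursors. Slco2b1 (-5.03 ± 0.34) and Cytip (-3.47 ± 0.47) are expressed by myeloid cells.

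Calls at 14 h numbered 3054, with 1526 higher and 1528 lower, of which 579 and 1062 changed by more than 2-fold. Of the 578 genes higher at 7 h, 481 were also higher at 14 h, where independent lists of these sizes would share 69.7, and of the 325 lower ones 250 were also lower, against 39.3.

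**Figure D2:**
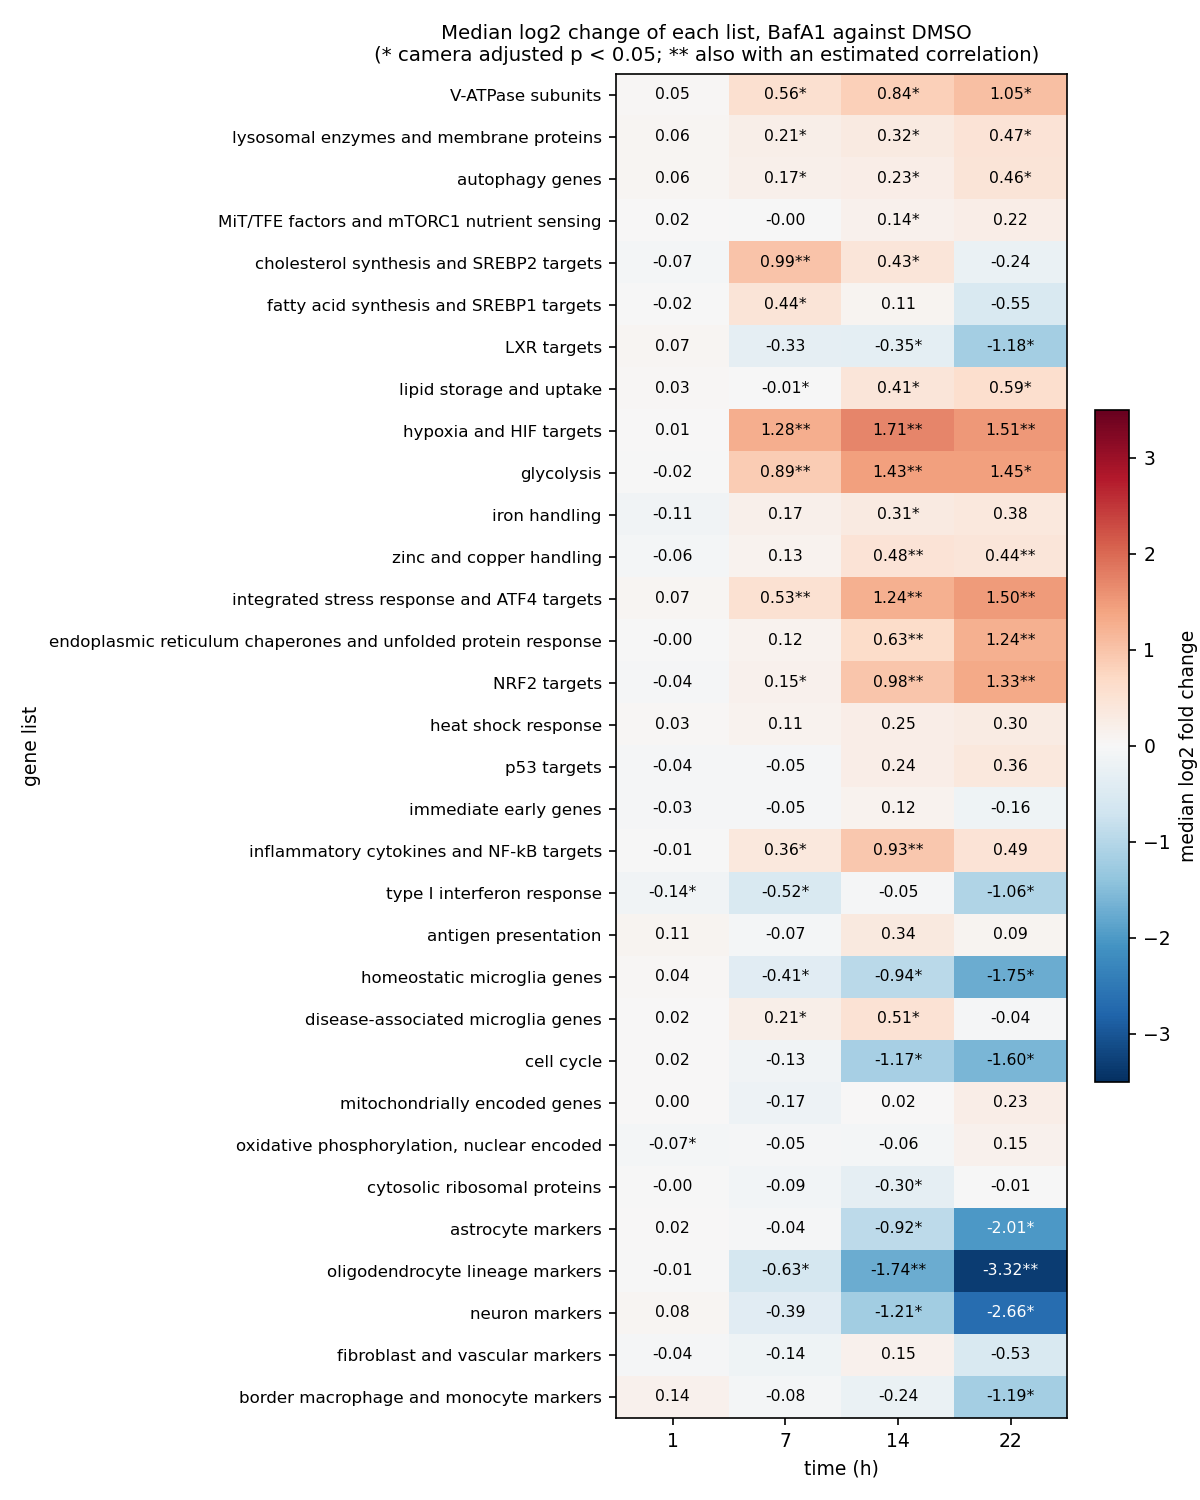
Each cell gives the median log2 change of a gene list (rows) with BafA1 against DMSO at 1, 7, 14 or 22 h (columns), coloured from blue (lower) to red (higher). A single star marks a camera adjusted p under 0.05 and 2 stars a call that also held with an estimated correlation; hypoxia genes stand at 1.28, 1.71 and 1.51 from 7 h on, and oligodendrocyte lineage markers at -0.63, -1.74 and -3.32.

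At 22 h the integrated stress response, NRF2 targets and endoplasmic reticulum chaperones were higher with BafA1 than with DMSO as lists, and oligodendrocyte lineage markers were lower. Mmp12 rose from 54.8 ± 7.26 to 1570 ± 226 CPM (SD, n = 3; log2 change 4.85 ± 0.35, adjusted p = 5.74e-11), Trib3 from 5.04 ± 2.43 to 116 ± 10.2 CPM (4.62 ± 0.42) and Lgals3, which marks damaged lysosomes, from 316 ± 61.4 to 3540 ± 292 CPM (3.49 ± 0.25). Ddit3 was at 3.87 ± 0.33, and 24 of 30 integrated stress response genes rose with 1 lower, also when adjusted over the list alone (median 1.5, camera adjusted p = 5.18e-11, and 0.0121 with an estimated correlation). Of the 22 endoplasmic reticulum chaperone and unfolded protein response genes 21 rose (22 adjusted over the list alone; median 1.24, adjusted p = 4.51e-13, and 0.00543 with an estimated correlation), Hspa5 from 560 ± 39.8 to 2600 ± 198 CPM and Dnajb9 by 2.46 ± 0.19. NRF2 targets rose in 15 of 19 cases, also when adjusted over the list alone (median 1.33, adjusted p = 1.18e-09, and 0.00625 with an estimated correlation). Prdx1 went from 1030 ± 129 to 5140 ± 544 CPM. Hypoxia genes rose in 21 of 27 cases with 1 lower, also when adjusted over the list alone (adjusted p = 3.45e-10, and 0.00278 with an estimated correlation). Glycolysis genes rose in 16 of 19 with 2 lower, also when adjusted over the list alone (adjusted p = 5.21e-09, and 0.0529 with an estimated correlation).

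V-ATPase subunits rose in 15 of 17 cases at 22 h and 1 fell, also when adjusted over the list alone (median 1.05, adjusted p = 2.23e-09, and 0.0676 with an estimated correlation). Atp6v0d2 was at 3.40 ± 0.38 and Atp6v1c1 at 2.47 ± 0.17. Lysosomal genes rose in 22 of 47 cases and fell in 7, also when adjusted over the list alone (adjusted p = 0.00412, and 0.761 with an estimated correlation). Gla was at 2.40 ± 0.18, Naglu at 1.78 ± 0.22 and Ctsc at -1.94 ± 0.22. Autophagy genes rose in 15 of 35 cases with 1 lower (16 and 1 adjusted over the list alone; adjusted p = 1.44e-05, and 0.0676 with an estimated correlation), and Sqstm1 went from 501 ± 54.6 to 3030 ± 176 CPM. On the MiT/TFE and nutrient sensing list 10 of 25 rose and 5 fell (12 and 5 adjusted over the list alone; adjusted p = 0.066, and 0.0451 with the replicate block). It was called without DMSO 22 h replicate 1 (0.0428) or 2 (0.0482) or BafA1 22 h replicate 3 (0.048). Cholesterol genes no longer moved as a list, with 4 of 24 higher and 7 lower (4 and 8 adjusted over the list alone; median -0.24, camera adjusted p = 0.481): Mvd (1.43 ± 0.20) and Insig1 (1.37 ± 0.17) were higher and Hmgcs1 (-0.57 ± 0.12) and Dhcr7 (-1.23 ± 0.30) lower. Fatty acid synthesis genes fell in 9 of 16 cases and 1 rose, also when adjusted over the list alone (adjusted p = 0.198). Elovl6 was at -2.04 ± 0.40 and Scd2 at -1.36 ± 0.18. LXR targets fell in 11 of 15 cases (12 adjusted over the list alone; median -1.18, adjusted p = 0.000417, and 0.189 with an estimated correlation), including the lipoprotein Apoe, from 9310 ± 439 to 3680 ± 646 CPM, and the cholesterol exporter Abca1 (-1.23 ± 0.24). Lipid storage genes had 9 of 18 higher and 4 lower (9 and 5 adjusted over the list alone; adjusted p = 0.0394, and 0.529 with an estimated correlation). The droplet coat gene Plin2 was at 1.53 ± 0.19 and Lpl at -2.00 ± 0.15. That list call ended without DMSO 22 h replicate 3 (adjusted p = 0.0595) and with the stricter filter (0.0521).

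Homeostatic microglia genes fell in 23 of 30 cases at 22 h and 1 rose (24 and 1 adjusted over the list alone; median -1.75, adjusted p = 7.58e-11, and 0.12 with an estimated correlation). Cx3cr1 went from 2240 ± 418 to 257 ± 56 CPM, Mef2c from 1210 ± 260 to 75.6 ± 18.3 CPM, Gpr34 from 82.9 ± 24.7 to 3.65 ± 0.947 CPM and P2ry12 from 26.1 ± 7.79 to 1.28 ± 0.879 CPM. Disease-associated genes again went both ways, 12 of 30 higher and 8 lower (12 and 9 adjusted over the list alone; median -0.04 and mean 0.15, camera adjusted p = 0.38). Type I interferon genes fell in 13 of 22 cases with 1 higher (14 and 1 adjusted over the list alone; adjusted p = 0.01, and 0.435 with an estimated correlation). Inflammatory genes rose in 7 of 24 and fell in 4, also when adjusted over the list alone (adjusted p = 0.135). Il1b fell from 344 ± 141 to 13.4 ± 5.16 CPM and its antagonist Il1rn rose by 2.36 ± 0.28. Cell cycle genes fell in 23 of 36 cases with 1 higher (25 and 1 adjusted over the list alone; median -1.60, adjusted p = 9.49e-07, and 0.19 with an estimated correlation), Cenpa by 2.94 (SE 0.31). Beside these groups, oligodendrocyte lineage markers fell in 11 of 12 cases, also when adjusted over the list alone (median -3.32, adjusted p = 2.39e-09, and 0.00625 with an estimated correlation): Pdgfra went from 129 ± 19.2 to 2.5 ± 0.495 CPM and Olig1 from 104 ± 15.3 to 2.62 ± 1.73 CPM. Astrocyte markers fell in 7 of 11 cases, also when adjusted over the list alone (median -2.01, adjusted p = 0.000376, and 0.273 with an estimated correlation). Sparcl1 was at -4.05 ± 0.28. Neuron markers fell in 4 of 5 cases, also when adjusted over the list alone (adjusted p = 0.000411, and 0.0529 with an estimated correlation). Map2 was at -3.44 ± 0.23. Border macrophage markers fell in 4 of 7 cases, also when adjusted over the list alone (adjusted p = 0.00296, and 0.103 with an estimated correlation). The mannose receptor Mrc1 was at -2.50 ± 0.23. Fibroblast and vascular markers had 2 of 9 lower, Fn1 (-2.61 ± 0.24) and Pecam1 (-3.79 ± 0.56), also when adjusted over the list alone (camera adjusted p = 0.294), and Acta2 was at 0.01 ± 0.62.

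**Figure D3:**
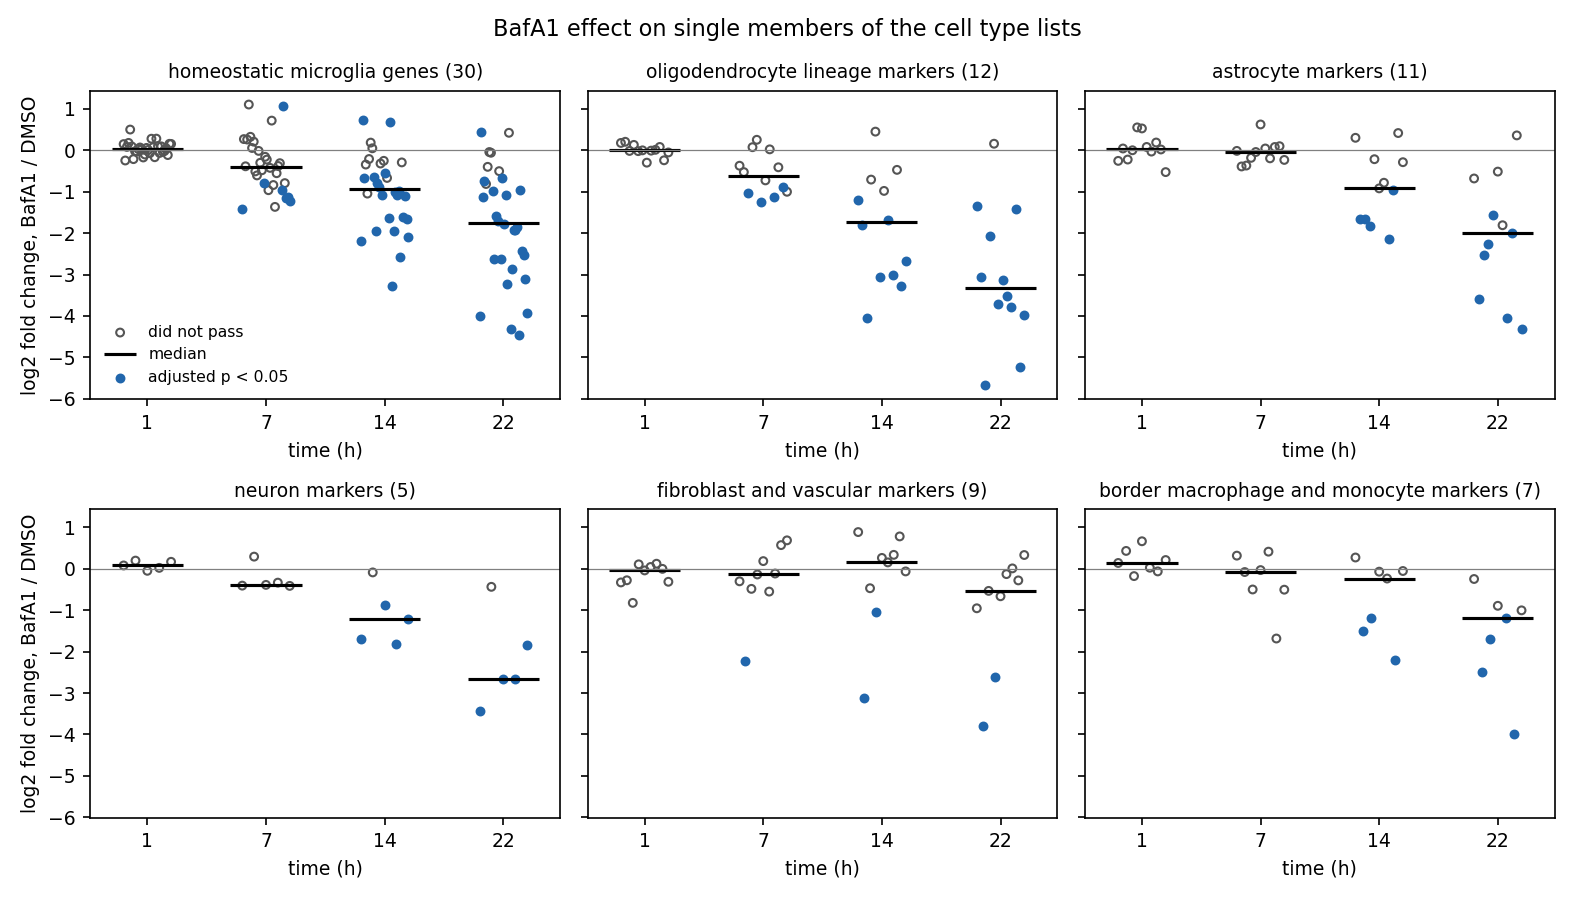
Points give the log2 change with BafA1 against DMSO of single members of 6 cell type lists at 1, 7, 14 and 22 h, filled where the adjusted p was under 0.05 and open otherwise, and black lines the list medians. At 22 h the medians are -1.75 for homeostatic microglia genes, -3.32 for the oligodendrocyte lineage, -2.01 for astrocytes, -2.66 for neurons, -0.53 for fibroblasts and vessels and -1.19 for border macrophages.

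The largest falls at 22 h included the contactin Cntn1, from 401 ± 45.1 to 9.96 ± 1.42 CPM (-5.31 ± 0.16, adjusted p = 6.73e-18), the glutamate receptor Grm5 (-5.92 ± 0.35), Nell2 (-5.04 ± 0.48) and the Na/K-ATPase subunit Atp1b2 (-5.01 ± 0.36), which are known from neural cells, and Slco2b1 (-6.58 ± 0.41). Pcdhga8, a protocadherin that shares its 3′ exons with its gene cluster, had no count in any BafA1 library at 22 h and was at least 79.5-fold lower than in DMSO, against a floor of 3 counts over the group. Calls at 22 h numbered 5050, with 2270 higher and 2780 lower, of which 966 and 2121 changed by more than 2-fold. Over all 4 times together 4678 genes were called. Of the 1526 genes higher at 14 h, 1193 were also higher at 22 h, where independent lists would share 274, and of the 1528 lower ones 1301, against 336.

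**Figure D4:**
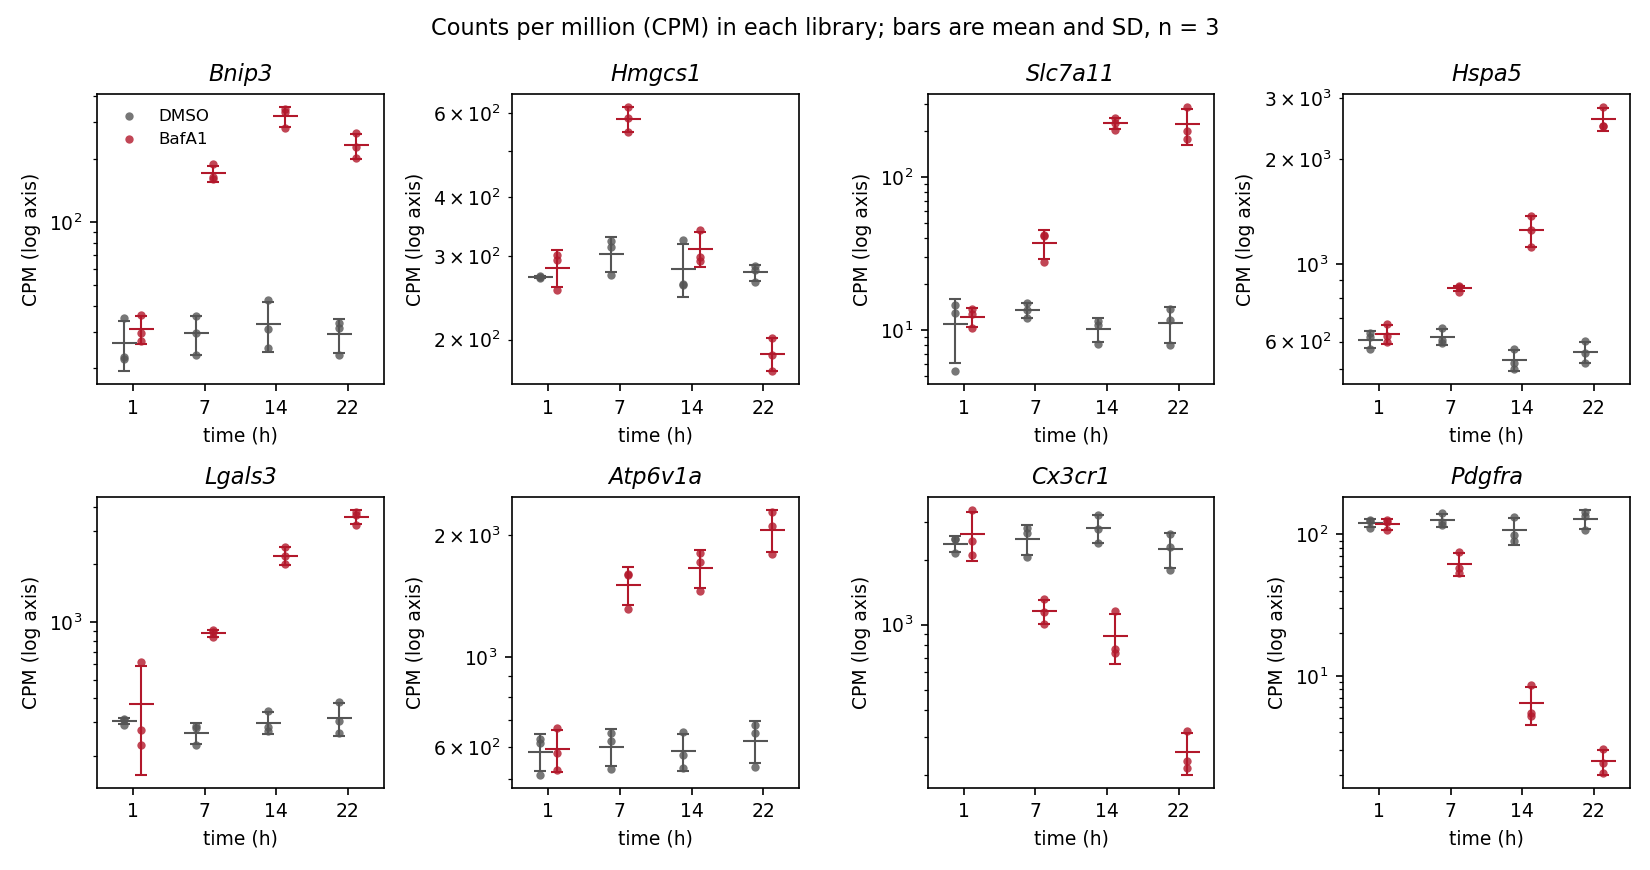
Points give CPM in each library on log axes against time in hours for 8 genes, with DMSO in grey and BafA1 in red; bars are the mean and SD of 3 libraries. Hmgcs1 rises to 584 CPM at 7 h and falls to 187 at 22 h with BafA1, and Pdgfra falls from 62.2 at 7 h to 2.5 at 22 h.

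The time course asked which effects of BafA1 differ between times. By the treatment by time F test, 2686 genes did (edgeR, Benjamini-Hochberg), and 4147 with the replicate number as a block. The 10 smallest p belonged to Cntn1, Pdgfra, the imprinted neuronal gene Nnat, Cspg5, Col11a1, Olfm2, Ptprz1 and Grm5, all with a lower fitted log2 change at each later time, and to Sqstm1 and Prdx1, with a higher one at each later time. Hypoxia genes gained most between 1 and 7 h (median 1.43, camera adjusted p = 7.06e-22, and 7.97e-05 with an estimated correlation), and 12 of 27 members passed that test upward. Cholesterol genes gained between 1 and 7 h (0.99, adjusted p = 2.5e-21, and 0.000119 with an estimated correlation), lost between 7 and 14 h (-0.56, 3.29e-06, and 0.0245) and lost again between 14 and 22 h (-0.70, 1.04e-07, and 0.0134). NRF2 targets gained between 7 and 14 h (0.74, adjusted p = 2.3e-14, and 0.00121 with an estimated correlation), and endoplasmic reticulum chaperones both between 7 and 14 h (0.58, 1.63e-09, and 0.0156) and between 14 and 22 h (0.45, 2.3e-09, and 0.0156). Genes called in opposite directions at 7 and 22 h numbered 23. They include Acat2, Dhcr7, Hmgcs1, Scd2 and Acsl3 of sterol and fatty acid synthesis and the metallothionein Mt1. Single genes whose effect differed numbered 282 between 1 and 7 h, 286 between 7 and 14 h and 251 between 14 and 22 h, and with the replicate block 678, 891 and 789. The count of 286 was lower without each of 12 libraries (143 to 277), and by more than 1.5 times without 6 of them: it went to 167 and 180 without DMSO 7 h replicate 1 and BafA1 7 h replicate 2, to 164 and 189 without DMSO 14 h replicates 2 and 3, and to 180 and 143 without BafA1 14 h replicates 1 and 2. The count of 251 was also lower without each of 12 libraries (121 to 244), and by more than 1.5 times without 4 of them: it went to 121 without DMSO 14 h replicate 1, to 166 and 152 without BafA1 14 h replicates 1 and 2, and to 132 without BafA1 22 h replicate 2.

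DMSO cultures themselves changed little with time. Rsrp1, an arginine and serine rich protein gene, rose from 60.9 ± 3.37 CPM at 1 h to 133 ± 12.2 at 7 h and 298 ± 24.1 at 22 h (log2 change 2.28 ± 0.15 at 22 h, adjusted p = 5.97e-10), and was the 1 gene called at 7 h. The transcription factor Pou2f2 rose by 1.76 ± 0.24 at 22 h and the chromatin regulator Ankrd11 by 1.48 ± 0.23, while the immediate early genes Egr1 (-1.27 ± 0.24) and Nr4a1 (-1.16 ± 0.25) were lower than at 1 h. Calls against 1 h numbered 1 at 7 h, 19 at 14 h (18 higher) and 51 at 22 h (47 higher), and with the replicate block 37 at 14 h and 163 at 22 h. The call of Lrig1 at 22 h rested on a level of 248 ± 376 CPM at 1 h and ended without DMSO 1 h replicate 2 or any 1 of the DMSO 22 h replicates, and those of Egr1, Nr4a1, Myh10 and Pcnt ended without single libraries too. Leaving out 1 library moved the 19 calls to 1, 0 and 1 without DMSO 1 h replicates 1, 2 and 3 and to 0 and 1 without DMSO 14 h replicates 2 and 3. It moved the 51 calls to 7, 6 and 16 without DMSO 1 h replicates 1, 2 and 3 and to 21 and 15 without DMSO 22 h replicates 2 and 3, and the 1 call at 7 h to 2 without DMSO 1 h replicates 1 or 3.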

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

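The tests of the markers of other cells were chosen only after those results were seen, as were the splits that redraw the times; the splits that redraw the treatment were fixed before the data were examined.

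The effect of BafA1 differed between times for 2686 genes, by the treatment by time test. It differed for 282 genes between 1 and 7 h, for 286 between 7 and 14 h and for 251 between 14 and 22 h. The 10 smallest adjusted p were 9.2e-16 for Cntn1, 2.12e-12 for Pdgfra, 1.33e-11 for Nnat, 1.95e-11 for Cspg5, 1.77e-10 for Col11a1, 4.1e-10 for Olfm2, 4.13e-10 for Ptprz1, 4.13e-10 for Sqstm1, 5.88e-10 for Grm5 and 6.91e-10 for Prdx1. At 22 h the contactin Cntn1 had a log2 change of -5.31, the glutamate receptor Grm5 -5.92, the collagen Col11a1 -4.43 and the receptor phosphatase Ptprz1 -4.24. The autophagy receptor Sqstm1 was at 2.60 and the peroxiredoxin Prdx1 at 2.32.

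With the treatment redrawn within each time in 100 splits, 3 splits gave as many treatment by time genes as the real 2686, with a highest other of 4250. All 3 are among the 51 splits that part every pair of replicate numbers, a share over 0.05, so chance is not excluded by the paired splits. For genes between 1 and 7 h, 1 split, the real one, reached 282 (highest other 6, also among the 51). Splits that kept the libraries of both times together but mixed those of 14 h called 0 genes here too. All libraries share 1 estimate of the spread, so this count cannot exclude chance. For the differences between 7 and 14 h, 5 of the 100 splits gave as many as 286 (highest other 1753), and for those between 14 and 22 h 16 gave as many as 251 (highest other 5887), so chance is not excluded there by this count. All of the larger splits kept the treated libraries of at least 1 compared time together, and splits that kept none together called no gene in these last comparisons. Together includes times at which the BafA1 and DMSO labels were swapped as a whole. A swap at 1 time, or mixing at the other, makes a difference between times of its own. These splits therefore cannot decide about chance for the treatment by time genes or the successive differences. With the times redrawn within each treatment, 1 of 100 splits, the real one, reached 2686 (highest other 1558), a count that does not use the pairs. No other of these splits kept the BafA1 libraries of each time together, so this count cannot exclude chance. For the 3 differences between successive times 11, 8 and 8 splits gave as many genes (highest other 453, 421 and 421), so chance is not excluded by that count, and all of these kept the BafA1 libraries of the times together.

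Pdgfra, among these 10 genes, is one of the oligodendrocyte lineage markers, which fell at 22 h together with astrocyte and neuron markers. A smaller share of all cells other than microglia would lower the markers of every other cell type. The fibroblast and vascular markers stood at -0.53 and those of the oligodendrocyte lineage at -3.32, a difference of 2.79 (SE 0.697 over list members). This difference cannot decide on a smaller share, because a list can hold genes also found on macrophages, whose levels need not follow the share of other cells. Pecam1 is such a gene, but it had the largest fall on its list (-3.79), so it does not account for the smaller fall of that list. Which other members microglia express was not tested. Astrocyte markers (-2.01) and neuron markers (-2.66) fell as well, and single fibroblast and vascular markers ranged from -3.79 to 0.33. Deeper BafA1 libraries do not account for the fall of the oligodendrocyte lineage markers, since the median in libraries thinned to equal totals was -3.43. Loss of oligodendrocyte lineage cells and changed expression within them cannot be told apart. The folds of the markers ran from -5.67 to 0.16, with a Q per degree of freedom of 41.3, but a loss of cells would give unequal folds too. With BafA1, 7 of the 12 markers had fewer than 10 counts in at least 1 library, and levels such as the 38.6 CPM of Mbp can come from other cells. A direct effect of BafA1 on these cells was not tested.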

How the results depend on the processing

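The libraries thinned to equal totals were chosen only after the data were seen, and the other alternatives were fixed before.

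Named genes mostly kept their calls: 3673 of 3855 comparisons of a called gene with an alternative stayed called in the same direction, 182 did not pass and 0 reversed. These comparisons leave out the changed count filters and the thinned libraries. Named DMSO changes held less well: of 13 calls, 8, 9 and 7 were lost without DMSO 1 h replicates 1, 2 and 3. Named genes were mostly picked for large changes, so their share does not stand for all calls. Of all 903 calls at 7 h, 61.4% to 79.2% were made again in the same direction when 1 of the libraries compared was left out. Of the comparisons of called lists 607 of 684 kept the call and 77 lost it. Of the 852 comparisons of uncalled lists 805 stayed uncalled, 45 were called in the same direction and 2 in the other. Of these 47, 29 came from leaving out 1 library, 10 from fry, 5 from the replicate block, 2 from thinned libraries and 1 from the stricter filter. With an estimated correlation 39 of the 57 list calls were lost, and with fry 8. RLE size factors moved the median of all genes by at most 0.00774. The cause of the differences below was not tested.

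Without a count filter the calls were 26 at 1 h, 5, 53 and 98 in DMSO at 7, 14 and 22 h, and 435 between 7 and 14 h. The stricter filter gave 1 and 32 in DMSO at 14 and 22 h. The replicate block gave 1555 at 7 h, 37 and 163 in DMSO at 14 and 22 h, 678, 891 and 789 for the successive differences and 4147 for treatment by time; it ended no call of a named gene or list. The block also called 5 lists that were not called without it: LXR targets (adjusted p = 0.0425) and endoplasmic reticulum chaperones (0.04) at 7 h, and MiT/TFE factors (0.0451), iron handling (0.0403) and mitochondrially encoded genes (0.0352) at 22 h. Thinned libraries gave 11 in DMSO at 14 h. With limma-voom DMSO had 5 and 23 calls at 14 and 22 h, and with DESeq2 29 and 98. DESeq2 called 424, 435 and 428 for the successive differences. The 6 libraries alone gave 17 in DMSO at 22 h. Lists called numbered 57, and 18 with an estimated correlation.

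Leaving out each library in turn gave 0 to 0 calls at 1 h, 573 to 804 at 7 h, 2170 to 2636 at 14 h, 4166 to 5014 at 22 h and 4109 to 5109 at any time. In DMSO it gave 1 to 2, 0 to 17 and 6 to 66 at 7, 14 and 22 h. The successive differences gave 192 to 281, 143 to 277 and 121 to 244, treatment by time 2328 to 2858, and lists 55 to 62. At 1 h lists were called in both directions when 1 library was left out. The lysosomal list, with a median of 0.055, was called lower without DMSO 1 h replicate 3 (median -0.058, adjusted p = 0.0429). It was called higher without DMSO 1 h replicate 1 (0.0297) or BafA1 1 h replicate 3 (0.00132). The ribosomal list, with a median of -0.004, was called higher without DMSO 1 h replicate 2 (median 0.091, adjusted p = 0.0449). It was called lower without DMSO 1 h replicate 3 (0.000753) or BafA1 1 h replicate 2 (1.43e-05). Their medians over all libraries left out were -0.125 to 0.189 and -0.133 to 0.091. Also at 1 h, glycolysis was called lower without BafA1 1 h replicate 2 (0.0396), and immediate early genes lower without DMSO 1 h replicate 2 (0.0297) or BafA1 1 h replicate 1 (0.0172). Without DMSO 1 h replicate 3 the integrated stress response (0.0192) and cell cycle (0.0151) were called higher, and without BafA1 1 h replicate 3 antigen presentation (0.00652) and disease-associated genes (0.0429). At 7 h LXR targets were called lower without DMSO 7 h replicate 3 (0.0478), endoplasmic reticulum chaperones higher without DMSO 7 h replicate 1 (0.0327) and cell cycle genes lower without BafA1 7 h replicate 3 (0.0471). In thinned libraries, where 11153 genes were tested in place of 12648, 77.3%, 73.1% and 78.4% of the calls at 7, 14 and 22 h were made again in the same direction. Fewer counts and fewer tested genes were not separated.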

Other observations

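The tests of small RNAs and of predicted genes at 14 h and both tests of the DMSO changes were chosen only after those results were seen.

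Metal handling genes rose in part. Fth1, the ferritin heavy chain, rose by 1.38 at 22 h, the transferrin receptor Tfrc by 1.97 and the iron transporter Slc11a2 by 2.17, and the iron regulator Hfe fell by 3.37. Iron genes rose in 3, 6 and 7 of 20 cases at 7, 14 and 22 h and fell in 1, 2 and 2 (4, 8 and 9 higher and 1, 2 and 2 lower adjusted over the list alone; camera adjusted p = 0.118, 0.0265 and 0.0573). At 22 h it was 0.0403 with the replicate block, 0.0287 without DMSO 22 h replicate 2 and 0.0406 without BafA1 22 h replicate 3. The call at 14 h ended without DMSO 14 h replicate 3 (0.0624), with the stricter filter (0.085) and in thinned libraries (0.0582), and was 0.19 with an estimated correlation. Zinc and copper genes rose in 3, 7 and 8 of 17 cases with 0, 1 and 1 lower, also when adjusted over the list alone (0.135, 0.00101 and 0.00481; 0.0121 and 0.0311 at 14 and 22 h with an estimated correlation). The zinc exporter Slc30a1 rose by 1.43 at 22 h. Heat shock genes rose in 1, 5 and 5 of 13 cases with 0, 1 and 1 lower, also when adjusted over the list alone (0.167, 0.186 and 0.174). p53 targets rose in 3, 5 and 6 of 22 cases and fell in 2, 2 and 3 (3, 7 and 6 higher and 2, 2 and 3 lower adjusted over the list alone; 0.842, 0.243 and 0.182), with Mdm2 at 1.83 at 22 h.

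Immediate early genes went both ways, rising in 6, 8 and 5 of 26 cases and falling in 5, 8 and 8 (7, 8 and 6 higher and 6, 8 and 9 lower adjusted over the list alone; adjusted p = 0.796, 0.838 and 0.892), with Atf3 at 1.85 and Fos at -2.48 at 22 h. Antigen presentation genes rose in 0, 2 and 3 of 14 cases and fell in 1, 2 and 4 (0, 2 and 4 higher and 2, 2 and 4 lower adjusted over the list alone; 0.722, 0.573 and 0.846), with H2-Ab1 at 2.92 and H2-DMa at -1.72 at 22 h. Mitochondrially encoded genes had 0, 0 and 2 of 15 higher (0, 0 and 0 adjusted over the list alone; 0.145, 0.475 and 0.0776). Their list was lower at 7 h without BafA1 7 h replicate 1 (0.0343), and higher at 22 h with the replicate block (0.0352) or without DMSO 22 h replicate 1 (0.0132). Nuclear genes of oxidative phosphorylation had 0, 0 and 8 of 33 higher and 0, 2 and 2 lower, also when adjusted over the list alone (0.247, 0.475 and 0.135, the last 0.0413 without DMSO 22 h replicate 2). Ribosomal protein genes fell in 0, 15 and 5 of 87 cases and rose in 0, 0 and 9 (0, 6 and 2 lower and 0, 0 and 7 higher adjusted over the list alone; 0.096, 3.22e-05 and 0.637). Their median at 14 h was -0.30, with an adjusted p of 0.696 with an estimated correlation. At 7 h the list was called lower with the stricter filter (0.0445), in thinned libraries (0.0433) and without DMSO 7 h replicate 3 (0.00107) or BafA1 7 h replicate 2 (0.00257).

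Of the 10 splits of the 6 libraries into 3 against 3, 10 gave as many genes as the real 0 at 1 h (highest other 63), 1 as many as 903 at 7 h (highest other 1), 1 as many as 3054 at 14 h (highest other 0) and 1 as many as 5050 at 22 h (highest other 0). In DMSO 2 splits gave as many as the real 1 at 7 h (highest other 1), 1 as many as 19 at 14 h (highest other 0) and 1 as many as 51 at 22 h (highest other 0). These splits are too few for a share under 0.05. Among the 4 splits that part all pairs of replicate numbers, the highest other was 0 in each comparison. With treatment redrawn within each time, 1 of 100 splits, the real one, gave as many genes as 4678 at any time (highest other 3909). It was also the only one to do so among the 51 splits that part every pair. Labels without effect at every time would seldom give this, a share under 0.05. Splits that kept the treated libraries of no time together called 0 genes, and all libraries share 1 estimate of the spread. The count therefore says nothing about chance at single times or for single genes.

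Rn7sk, which fell at 7 h and 14 h to 32.3 and 32.6 CPM, was not called at 22 h (154 in DMSO and 209 with BafA1). Lower capture of RNAs without a poly(A) tail would lower other small RNAs. The median of the 11 other small RNA genes tested was -0.53 (SE 0.274) at 7 h and -0.17 (SE 0.592) at 14 h, with 3 of them called lower at 14 h. These were Scarna2 (-3.62), Rpph1 (-3.77) and Rnu1a1 (-2.40), named after their values were seen, at mean log2 CPM of 1.19 to 2.39. They were at -2.35, -1.19 and -1.60 at 7 h and 0.02, -0.51 and 0.39 at 22 h, not called. The other small RNA genes were not called at 14 h. Lower capture and a fall of Rn7sk itself cannot be told apart, because the small RNAs moved unequally, the medians have wide errors and few small RNAs were counted. Reads moved to copies under predicted-gene names stay open too: the predicted genes changed by 1710 CPM in sum (SE 3400) at 7 h, where Rn7sk lost 246 CPM, an error larger than the loss. At 14 h, where Rn7sk lost 259 CPM, they changed by -5330 CPM in sum (SE 1550), which shows no net gain. That sum includes falls of other predicted genes. Those that rose at 14 h gained 3340 CPM together. At 1 h, where Rn7sk had a log2 change of 0.078 and was not called, those that rose gained 3380 CPM. A sum of rises alone is large without any moved reads, so it neither shows nor excludes a gain the size of the loss. The predicted genes Gm56244, Gm55636, Gm55604 and Gm54754 had log2 changes of -4.05, -3.38, -4.30 and -3.24 at 7 h, where gaining copies would rise. They were chosen because they moved with Rn7sk, and whether they are its copies is not given in the sources used here, so they do not settle it. No biological explanation was tested.

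The 47 genes that rose in DMSO between 1 and 22 h had a median longest transcript of 7095 bases against 3349 for all genes tested. A trend of the change with transcript length may add to the rise: their median log2 change was 1.29 before and 1.12 after that trend was taken off. The trend over all genes was weak (Spearman rho 0.159) and took little off that median. The median length of the 47 genes lay at percentile 100 of 10000 lists of genes at like levels. Their median change mixes long genes with short ones of larger rise. Zfhx3, a long gene chosen after its values were seen, went from 0.725 to 0.378 when the trend was taken off. The genes were picked for their rise, so these values do not decide how much length adds. Some of the 47 were short genes with few counts, such as Gm12155 (160 bases, log2 change 5.73, mean log2 CPM 2.55), chosen after its values were seen. In thinned libraries 31 of the 47 were called again, which decides nothing about depth: mean totals were already alike, 2104620 counts at 1 h and 2124547 at 22 h. In BafA1 cultures the same genes had a median of 1.06 between 1 and 22 h, and 32 of the 47 passed, while 9 had a lower fitted value, such as Pou2f2 at -1.41. Against DMSO at 22 h their median with BafA1 was -0.595. The genes were picked for high values in those same DMSO libraries, so a lower median can arise without any effect of BafA1. What time in culture changes was not tested.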
